A study of Homo sapiens with 6 samples.

How the data were processed

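Small RNAs of PC3 cells, a human prostate cancer line, were measured on 6 one-colour Agilent miRNA arrays. Samples came from cells transfected with a pool of siRNAs against UHRF1 (3 arrays) or with a non-targeting siRNA pool (3 arrays), with RNA taken at 72 h. Per the labels' protocols, total RNA was extracted with Trizol, treated with DNase, and 100 ng was labelled with Cy3. The labels call the samples independent replicates. The replicate numbers of 1 control array differ between its title and its source name, and the title's number was used.

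Each deposited scanner file held spot intensity values on a linear scale. Per the file headers, Agilent Feature Extraction 10.7.3.1 made them, with background subtracted in its processed signal. The submitters' processing notes name version 10.7.7.1, and the difference was not resolved. The files also held Agilent's total gene signal, another intensity per entry, in which an entry not detected was listed at 0.1. In the deposited table of the whole series, each entry had a value per array, in a unit the sources used here do not give. Its values followed the order of each array's total gene signal (Spearman correlation of 1 over detected entries on every array). Control entries included, the arrays shared nearly the same distribution, with a median of 0.1 over human entries on every array. They were therefore read as quantile-normalized, uncentred linear values, which no source states, and used on the log2 scale as an alternative only. No lower limit was applied to them. Log2 changes in that table of entries not detected on some arrays therefore depend on the low values listed there. No further column of per-sample values was left unused.

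The array carried 851 human and 88 viral entries, each with 16 spots. Most human entries had 2 probes (483 entries) or 4 probes (308), with 3 probes for 56 and 1 probe for 4. Spots marked as outliers were left out, the processed signals of the spots of a probe were averaged, and the probes of an entry were averaged. Detection was taken from the scanner software's call per entry. Only 43 human entries were detected on all 6 arrays, so each array was scaled to the 75th percentile of those entries. Values below a floor of -4.25 on the log2 scale, the median over arrays of the lowest detected level, were set to it. Levels are therefore log2 of signal relative to that percentile, and folds of entries near the floor are understated. An entry not detected on any array of a group has only a bound there. Its fold is given as "at least", from the mean level of the other group against, per array, the higher of the lowest detected level and the entry's own.

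Entries detected on all 3 arrays of at least 1 group were tested, 74 in all, with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8), without a replicate block. A Benjamini-Hochberg adjusted p below 0.05 made a call. The 24 miRNA lists were fixed before the data were examined, as were the tests and all alternatives not said to be added. Lists with at least 5 tested members (4 lists) were tested with limma's camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. The camera test compares a list with the other tested entries, so its direction is relative to them. Shorter lists are described by their members. Differences between arrays used an exact two-sided permutation test in scipy, whose smallest p with 3 against 3 arrays is 0.1.

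The named entries were those with an adjusted p below 0.05 and no overlap between groups, up to 12 per direction by size of change. Of each list, the 2 tested members with the smallest p were named, fewer than the rule's maximum, for space. On simulated values with the spread of the UHRF1 siRNA against control siRNA comparison (74 entries, 100 simulations), the test recovered 51.0% of changes of 0.5, 80.9% of changes of 1 and 96.1% of changes of 2 on the log2 scale. False calls made up 4.20% of all calls. The simulated values had independent noise per entry, with no floor, no scaling step and no slide difference. These rates may therefore not hold for the calls on the real arrays.

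The headers placed UHRF1 siRNA replicate 1 and all 3 control arrays on slide 1 and scan day 1, and UHRF1 siRNA replicates 2 and 3 on slide 2 and scan day 2. A fit with slide as a block therefore takes its estimate from slide 1 alone, from 1 UHRF1 siRNA array against 3 controls, and is given beside the main results. Slide 2 held 1 group only. Relative to spot noise, control arrays 2 and 3 were the closest pair, while UHRF1 siRNA arrays 2 and 3 had the smaller SD of log2 differences (0.12 against 0.14). The probes of the 2 controls differed by 3.22 times the variance expected from spot noise over 51 probes, against 19.5 to 66.8 for the other pairs within a group, and all arrays were kept as separate samples.

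The normexp alternative was planned on mean spot signals, a column the files did not hold. It was run on median spot signals instead. Other alternatives were a replicate block, leaving out each array, other scalings, other summaries, other filters and floors, slide as a block, and other variance models. Leaving out an array also redid the filter, the scale and the floor on the remaining arrays. Values without an array therefore include a change of scale. GC content was not tested because no probe sequences were used here. UHRF1 mRNA is not measured by this array, so the knockdown was not checked here. Gene neighbours were taken from a RefSeq table of GRCh38.p14, and no coordinates are given because the files name no genome build. The number of arrays limits the precision.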

Results

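Levels of small RNAs were compared between PC3 prostate cancer cells given siRNAs against UHRF1 and cells given non-targeting siRNAs, with 3 arrays per group at 72 h. UHRF1 is a ubiquitin ligase that brings DNMT1, the maintenance DNA methyltransferase, to replicating DNA. The comparison asked which miRNAs change when UHRF1 is silenced.

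By the scanner software's call, more entries were detected after UHRF1 silencing. The UHRF1 siRNA arrays detected 75, 86 and 97 of 851 human entries, and the control arrays 57, 59 and 70. The means were 86 ± 11 and 62 ± 7 (SD, n = 3 each; exact permutation p = 0.1, two-sided, the smallest these arrays allow). Within slide 1, the single UHRF1 siRNA array detected 75, above all 3 controls. By a rule of positive and significant spots the groups overlapped (213, 189 and 255 against 235, 170 and 225), and the means differed by 9. No array detected over 11.4% of the entries. The 75th-percentile signal differed less, with log2 means of 6.16 ± 0.24 and 6.04 ± 0.59 (SD, n = 3; exact permutation p = 1). Control replicate 1 was the dimmest array, with a 75th percentile of 41.1 against 59.1 to 84.8 on the other arrays.

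The composition of the signal also differed. Entries of the list of fragments of other small RNAs, which are array names since traced to tRNA, vault RNA, snoRNA or U2 RNA, held 66.2% ± 1.69 of the summed signal of detected entries in UHRF1 siRNA arrays. They held 25.6% ± 1.33 in controls (SD, n = 3; exact permutation p = 0.1, two-sided). Most of it was miR-720, a tRNA-derived entry, with 61.5% ± 1.55 against 24.2% ± 1.21. Shares are of array signal, not of molecules. Within slide 1 the UHRF1 siRNA array stood at 65.9%.

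**Figure D1:**
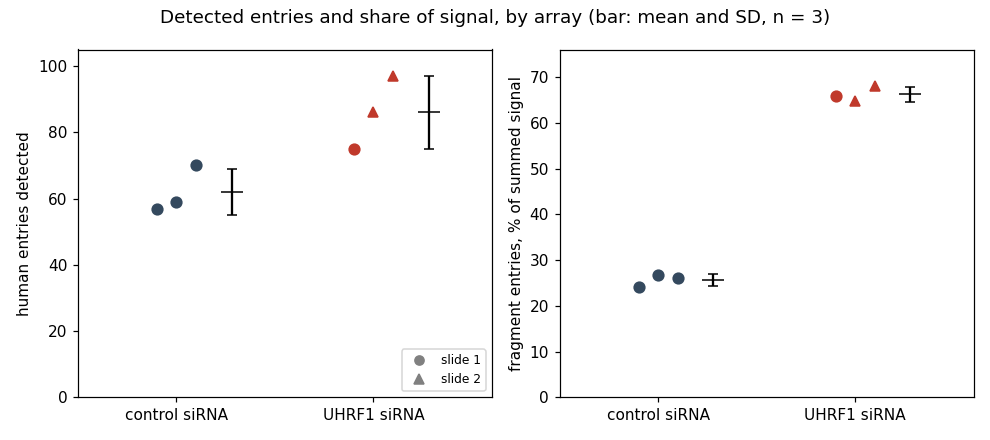
Number of human entries detected (left) and share of summed detected signal from fragment entries in percent (right), for each array by group, with mean and SD (n = 3) and the slide marked. The UHRF1 siRNA arrays lay between 64.7% and 68.1% and the controls between 24.1% and 26.7%.

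Of 74 tested entries, 23 rose and 9 fell after UHRF1 silencing. The largest rises were those of miR-1246, an entry traced to U2 RNA, and of miR-1290. Falls were smaller, and included miR-425, miR-30d, miR-15b and all 4 detected members of the miR-320 family. All 32 calls had groups that did not overlap, as did 43 of the 74 tested entries. Chance gives 10% before the detection filter, which itself favours separation. Of the 43 entries detected on all arrays, 21 did not overlap. At an unadjusted p below 0.05, 39 entries passed.

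Several of the risen entries were not detected on any control array. The level of miR-1246 was 0.24 ± 0.08 against -4.19 ± 0.10 (SD, n = 3), at least 20.3-fold higher (adjusted p = 7.90e-07). That of miR-1290 was at least 11.6-fold higher, miR-483-5p, which lies in IGF2, at least 4.97-fold and miR-1268 at least 4.71-fold. The bound was 3.82-fold for miR-1915 and 3.64-fold for miR-1202. These bounds hold only for the scanner's processed signal averaged over the probes of an entry. With normexp background correction and offset, the log2 change was 0.88 for miR-1246 (4.42 here) and 0.47 for miR-1290. The others were not called, with 0.098 for miR-483-5p, 0.20 for miR-1268, -0.021 for miR-1915 and -0.025 for miR-1202. On the brightest probe alone, with the same processed signal, miR-483-5p, miR-1915 and miR-1202 stood at 1.37, 0.86 and 0.93, below their bounds. In the setting called without a floor, negative signals, which have no log, were set to the smallest positive scaled value of any human entry. There miR-1290, miR-483-5p, miR-1915 and miR-1202 had larger values (8.32, 7.42, 7.83 and 6.70) but were not called (adjusted p = 0.143, 0.171, 0.137 and 0.213). Their signals on control replicate 1 were negative, so these sizes depend on that smallest value. In all, 10 entries were detected on all UHRF1 siRNA arrays and no control array, and 0 the other way round.

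The remaining entries of the 12 largest rises were detected on at least 1 control array. The level of miR-720 was 6.42 ± 0.12 against 3.75 ± 0.09, a log2 fold change of 2.68 ± 0.10 (SE, adjusted p = 6.90e-06). That of miR-923 was higher by 2.70 ± 0.12 (adjusted p = 9.93e-06). The change was 3.13 ± 0.52 for miR-1274b, detected on 2 control arrays, 2.93 ± 0.15 for miR-1274a, detected on 1, 2.57 ± 0.52 for miR-1260 and 2.07 ± 0.12 for miR-1308. With slide as a block, miR-1274b, miR-1260 and miR-1268 stood at 3.23, 2.13 and 2.39 but were not called (adjusted p = 0.0605, 0.135 and 0.0538). Nor were they without a detection filter, where the values were unchanged (adjusted p = 0.279, 0.389 and 0.263). Without a floor miR-1274a, whose signal on control replicate 1 was also negative, stood at 7.37 and was not called (adjusted p = 0.196). miR-1274b stood at 2.26 without control replicate 1, and was not called in the deposited table (adjusted p = 0.218). With normexp and offset, miR-1274a and miR-1308 were not called (0.21 and 0.34), and miR-923, miR-1274b and miR-1260 stood at 1.17, 1.49 and 0.77. With normexp without offset miR-1260 was not called (1.40, adjusted p = 0.144). Quantile normalization sets the difference of miR-720, the brightest human entry on every array, to 0 by construction.

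Among the falls, miR-425 fell by 1.15 ± 0.18 on the log2 scale (SE, adjusted p = 0.00398), and was detected on 1 UHRF1 siRNA array. It was not called with normexp and offset (-0.23, adjusted p = 0.447), when scaled over all human entries (-0.78, adjusted p = 0.268) or without a filter (adjusted p = 0.219). Of the 9 falls, none was called over all human entries or with normexp, 1 (miR-425) without scaling and 1 (let-7d) without a filter. miR-30d fell by 0.85 ± 0.26 (adjusted p = 0.0406). Its call was lost without UHRF1 siRNA replicate 1, 2 or 3 or control replicate 2 (adjusted p = 0.156, 0.0709, 0.115 and 0.0619) and with slide as a block (-1.12, adjusted p = 0.102). miR-320b, miR-320d, miR-320c and miR-320a, whose near-identical sequences array probes do not reliably separate, fell by 0.69, 0.68, 0.59 and 0.38. None of these was called with slide as a block (-0.44, -0.43, -0.37 and -0.25, adjusted p = 0.0605, 0.156, 0.196 and 0.181). Without UHRF1 siRNA replicate 2 or 3, miR-320d, miR-320c and miR-320a were not called (-0.63 and -0.60, -0.56 and -0.51, -0.40 and -0.31). Neither was miR-320c without control replicate 2 (-0.64), nor miR-320a without control replicate 2 or 3 (-0.34 and -0.40), and without control replicate 1 it stood at -0.67. miR-15b, let-7d and miR-23a fell by 0.65, 0.30 and 0.29. The slide block kept the calls of miR-15b and let-7d and not that of miR-23a (-0.22, adjusted p = 0.0920). let-7d and miR-23a stood at -0.55 and -0.54 without control replicate 1. Without UHRF1 siRNA replicate 2 or 3 or control replicate 2 or 3 neither was called (let-7d at -0.31, -0.29, -0.28 and -0.32, miR-23a at -0.29, -0.26, -0.32 and -0.27). When scaled over all human entries, miR-320a and let-7d stood at 0.041 and 0.13.

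**Figure D2:**
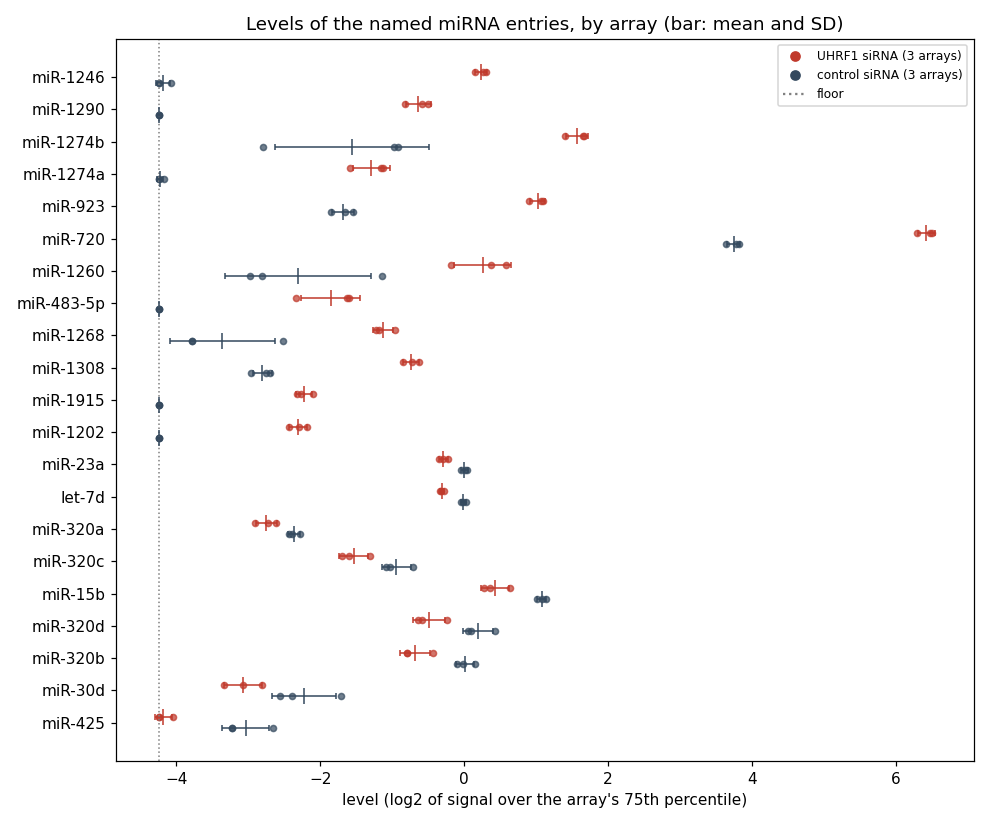
Level of each named entry on each array (log2 of signal over the array's 75th percentile), with mean and SD of each group (n = 3) and the floor of -4.25. For miR-720 the groups stood at 6.42 and 3.75, and for miR-23a at -0.29 and 0.0040.

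With slide as a block, 20 entries were called, 17 higher and 3 lower, of which 18 were among the 32. Within slide 1 all 32 kept their direction. This had to be so, since the groups of these calls did not overlap, and it says nothing on the slide. The split of rises to falls moved with the scaling and with the detection filter. It was 23 to 9 here, 19 to 20 with median scaling, 16 to 17 with quantile normalization, 16 to 1 without scaling, 16 to 0 when scaled over all human entries and 17 to 18 in the deposited table. Over the 43 entries detected on all 6 arrays it was 8 to 6, and their median log2 fold change was -0.0047. The other tested entries passed the filter through 1 group only. Of these, 14, 5 and 10 were detected on all UHRF1 siRNA arrays and on 2, 1 and 0 control arrays. Only 1 and 1 were detected on all control arrays and on 2 and 1 UHRF1 siRNA arrays. Without control replicate 1, falls numbered 23, and without UHRF1 siRNA replicate 2 or 3 they numbered 3. With normexp background correction 7 entries rose and 0 fell, and 23 of the 32 calls kept their direction. The median over tested entries was 0.29, and shifted from it by -0.32 with median scaling, -0.41 with quantile normalization and 0.31 when scaled over all human entries. It shifted by -0.35 without control replicate 1, where the scale was also redone.

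The list of fragments of other small RNAs rose as a group. Of its 7 tested members, 6 rose and 0 fell, and 6 also passed when adjusted over the list alone. Its median log2 fold change was 2.68 (camera adjusted p = 0.00262, fry adjusted p = 2.16e-06). Placing miR-1246, not detected on any control array, at its bound left it above the median, so the median could not move. The adjusted p was 0.0864 with an estimated correlation. The median was 0.77 with normexp and offset and 4.99 in the deposited table. The latter was the value of miR-1280, detected on 1 control array, in a table used without a lower limit. Its size therefore depends on the low values listed where an entry was not detected. With slide as a block the median was 2.73 (camera adjusted p = 0.0231). The member that did not pass was miR-1280, at 1.32 ± 0.59 (SE, adjusted p = 0.116), named after its value was seen, and 1.74 without control replicate 1 (adjusted p = 0.00350). It was also called without scaling (1.44), over all human entries (1.75) and with array weights (2.03). With normexp with and without offset it turned to -0.053 and -0.029.

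The let-7 family, which restrains growth, had 8 tested members, of which 1 fell (let-7d) and 0 rose, with 0 when adjusted over the list alone. let-7a differed by -0.22 ± 0.10 (adjusted p = 0.116), and by -0.53 without control replicate 1 (adjusted p = 0.00967). let-7d stood at -0.55 without that array. The family's median was -0.10 (camera adjusted p = 0.0577). It was -0.04 with slide as a block, and turned to 0.023 without scaling. Relative to the other tested entries, camera called the family lower with median scaling (-0.43, camera adjusted p = 0.0110) and quantile normalization (-0.40, 0.0280). The same held for the deposited table (-0.48, 0.0375) and total gene signal (-0.12, 0.0461). The median over all tested entries in these settings was -0.034, -0.12, 0.28 and 0.35. On slide 1 alone the family's median was -0.036, against 0.33 over all tested entries. Leaving out control replicate 1, which also changed the scale, gave -0.40 and a camera adjusted p of 0.00541. Leaving out UHRF1 siRNA replicate 2 gave -0.094 and 0.0405.

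The miR-17-92 cluster and its paralogs, known as oncogenic clusters, had 8 tested members. Of these, miR-19b and miR-20a rose, by 1.21 ± 0.36 and 0.62 ± 0.17 (SE, adjusted p = 0.0373 and 0.0304), and 0 fell. None passed when adjusted over the list alone. The median was 0.08, while camera's direction was down (adjusted p = 0.406). Neither was called with slide as a block (1.26 and 0.82, adjusted p = 0.196 and 0.0637), nor with median scaling (0.88 and 0.29), quantile normalization (0.95 and 0.26) or no scaling (1.33 and 0.74). Both calls were lost without UHRF1 siRNA replicate 1, 2 or 3 (miR-19b at 1.18, 1.22 and 1.23, miR-20a at 0.51, 0.68 and 0.66). Without control replicate 1, miR-19b stood at 0.53 and miR-20a at 0.21 (adjusted p = 0.129), and the median at -0.31. The median was -0.24 with median scaling.

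In the miR-23-27-24 clusters, members went both ways. miR-27a rose by 1.02 ± 0.10 on the log2 scale (SE, adjusted p = 0.000377) and by 0.98 within slide 1, but was not called without scaling (1.14, adjusted p = 0.0776), over all human entries (1.44, adjusted p = 0.0652) or with normexp and offset (0.36), while miR-23a fell by 0.29 ± 0.09 (adjusted p = 0.0377). When scaled over all human entries miR-23a stood at 0.13. It was not called with slide as a block (adjusted p = 0.0920), and without control replicate 1 it stood at -0.54. Of 4 tested members, 3 passed when adjusted over the list alone.

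Among miRNAs reported as silenced by DNA methylation in cancer, 9 of 63 entries were detected on any array. Of 5 tested, miR-31* rose, by 0.85 ± 0.12 (SE, adjusted p = 0.00280), and 0 fell. miR-23b differed by -0.56 ± 0.20 (adjusted p = 0.0640). The call of miR-31* was lost with quantile normalization (0.64, adjusted p = 0.392), without scaling (0.97, adjusted p = 0.104), over all human entries (1.27, adjusted p = 0.0871), in the deposited table (2.78, adjusted p = 0.380) and without a filter (adjusted p = 0.103). miR-31* and miR-23b stood at 0.55 and -0.94 without control replicate 1 (adjusted p = 0.00946 for miR-23b). The median was -0.23 (camera adjusted p = 0.406), 0.10 with slide as a block, and 1 member passed when adjusted over the list alone. Leaving out an array put it at -0.048 (UHRF1 siRNA replicate 1), -0.099 (replicate 2) and -0.40 (control replicate 3). The list of reported regulators of DNA methyltransferases took in miR-29b-1* only by its name, as a passenger strand of miR-29b. The entry miR-29b itself was detected on 1 UHRF1 siRNA array and was not tested. miR-29b-1* rose, by 0.74 ± 0.14 (adjusted p = 0.00743). Its call was lost with quantile normalization (0.56, adjusted p = 0.247), median scaling (0.41, adjusted p = 0.0610), no scaling (0.86, adjusted p = 0.0683), all human entries (1.08, adjusted p = 0.115), the deposited table (2.22, adjusted p = 0.410) and no filter (adjusted p = 0.263). miR-29a differed by 0.30 ± 0.10 (adjusted p = 0.0513), and by 0.0039 without control replicate 1 (adjusted p = 0.971). It was called lower with quantile normalization (-0.22) and in the deposited table (-0.25), and higher with slide as a block (0.41, adjusted p = 0.0487). With normexp and offset miR-29b-1* and miR-31* turned to -0.17 and -0.058. Of 3 tested, 1 rose, and 2 passed when adjusted over the list alone. Of 3 passenger strands tested, miR-31* and miR-29b-1* rose, also when adjusted over the list alone.

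miR-210, a hypoxia-induced miRNA, rose by 1.27 ± 0.24 (SE, adjusted p = 0.00743), and miR-638 was at least 1.66-fold higher. With normexp and offset these turned to -0.042 and -0.13, and miR-638 stood at 0.43 on the brightest probe alone, below its bound. When scaled over all human entries miR-638 was not called (0.97, adjusted p = 0.132). All 3 tested hypoxia and stress miRNAs passed when adjusted over the list alone. miR-21, an oncogenic miRNA on the innate-response and the prostate and androgen-linked lists, rose by 0.99 ± 0.19 (adjusted p = 0.00743). Neither miR-210 nor miR-21 was called with slide as a block (1.46 and 1.12, adjusted p = 0.0538 for both), nor without UHRF1 siRNA replicate 1 (1.17 and 0.92, adjusted p = 0.0519 and 0.0518). Leaving out control replicate 1 put them at 0.78 and 0.55. Neither was called without scaling (1.30 and 1.11, adjusted p = 0.0683 and 0.128) or without a filter (adjusted p = 0.340 and 0.301), nor was miR-21 when scaled over all human entries (1.42, adjusted p = 0.0870). miR-210 was also not called with quantile normalization (0.83, adjusted p = 0.255) or in the deposited table (2.70, adjusted p = 0.380). miR-21 was the 1 call on each list, of 2 and 3 tested, also when adjusted over the list alone. The other named members were miR-125a-5p at 0.35 ± 0.40 and miR-125b at 0.29 ± 0.12 (adjusted p = 0.492 and 0.105). miR-125a-5p was called without control replicate 1 (0.57).

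In the miR-15/16 family, miR-15b fell and miR-15a stood at 0.50 ± 0.27 (SE, adjusted p = 0.179), with 1 of 3 passing when adjusted over the list alone. In the miR-30 family the 1 tested member, miR-30d, fell, also when adjusted over the list alone, but its call was lost as given above. No member passed either way among the 3 tested of the miR-99/100 and miR-125 group (miR-100 at -0.25 ± 0.13) or the single tested members of 3 lists. These were miR-107 of the p53-linked list (0.10 ± 0.10), miR-183 of the miR-183-96-182 cluster (-0.26 ± 0.22) and miR-196b of the HOX-cluster list (-0.23 ± 0.26). Without control replicate 1, where the median over tested entries shifted by -0.35, miR-183 and miR-100 were called (-0.72 and -0.47). miR-100 was also called without UHRF1 siRNA replicate 1 (-0.38), with median scaling (-0.58) and with array weights (-0.30). miR-183 was also called in the deposited table (-1.29), with total gene signal (-0.45) and with array weights (-0.55). miR-107 and miR-15a turned to -0.19 and -0.059 without control replicate 1. With median scaling miR-107 was called lower (-0.23).

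**Figure D3:**
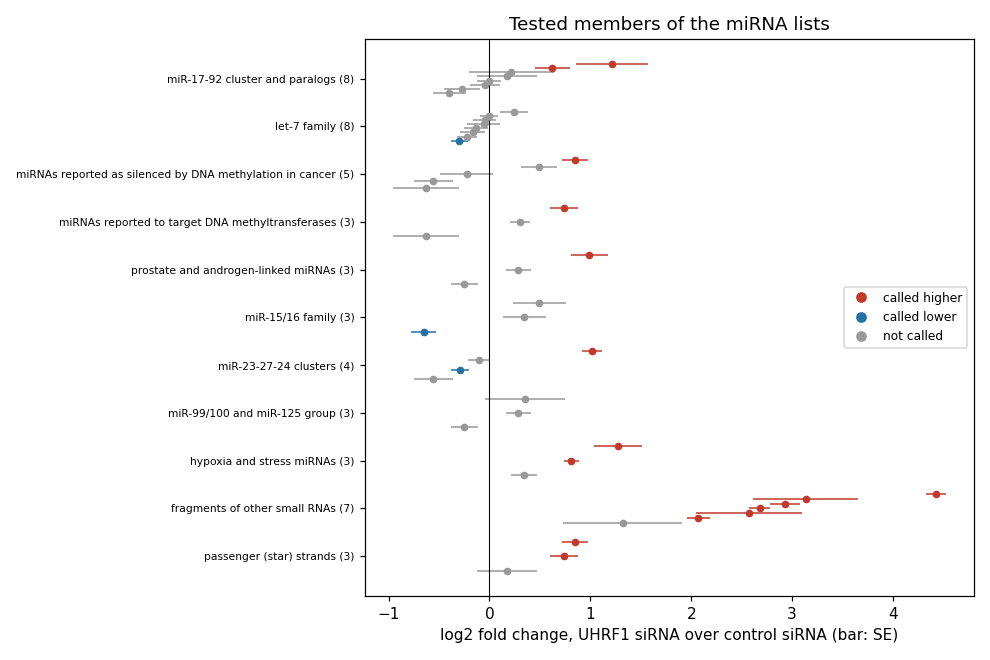
Log2 fold change (UHRF1 siRNA over control siRNA, with SE) of each tested member of the lists with at least 3 tested members, coloured by call. The fragment entries lay between 1.32 and 4.42, and the let-7 family between -0.30 and 0.24.

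Members of 7 lists were detected on no array. These were the miR-200 family (9 entries), the chromosome 19 cluster (46), the DLK1-DIO3 cluster (66), the pluripotency clusters (17), miRNAs reported to target UHRF1 (19), the miR-181 family (7) and markers of other cell types (25). Of 20 entries of the Xq27 clusters, 1 was detected and 0 were tested.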

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

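The tests of explanations in this part were chosen after the results were seen. The settings without scaling, without control replicate 1 and, for single entries, with slide as a block were planned.

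All 5 hur and mr entries detected on every array, which the array marks as controls and the comparisons do not use, were higher on every UHRF1 siRNA array than on every control array. What they measure is not given in the sources used here. The log2 difference of unscaled signal was 0.83 for hur_1, 1.19 for hur_2, 1.11 for hur_4, 1.82 for hur_6 and 0.53 for mr_1. After scaling, mr_1 no longer separated the groups. The viral entry ebv-miR-BART13 was detected on the 2 UHRF1 siRNA arrays of slide 2 with a mean signal of 4.37, and was listed at 0.1 elsewhere. The UHRF1 siRNA array of slide 1 did not detect it.

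The fragment entries were higher in the UHRF1 siRNA arrays. Within the UHRF1 siRNA group, slide 2 differed from slide 1 by a median of -0.075, which argues against the slide and scan day as the cause. Without scaling the median difference was 2.80, and without the dim control array it was 2.37, so neither of these accounts for it. Background handling was not excluded. With normexp with and without offset, 4 and 3 of the 7 tested fragment entries were called higher, and with offset their median was 0.77. Breakdown of longer RNAs in the preparations was not tested, as no RNA integrity values were used here. It stays open, as does an effect of UHRF1 silencing.

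The miR-27a entry rose over miR-23a and miR-24, each with a gene that neighbours that of miR-27a, a pattern chosen after the values were seen. The difference of the log2 ratio within arrays was 1.22, which a single factor per array cannot change. Between slides within the UHRF1 siRNA group it was 0.17, without the dim control array it was 1.18, and the lower of the 2 probes gave 1.20. These values argue against the slide and scan day, the dim array and a single probe. Background handling was not excluded. With normexp and offset miR-27a and miR-23a lay closer together, at 0.36 and -0.13, and without offset they stood at 0.65 and -0.21. An effect of UHRF1 silencing stays open and untested.

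The falls depended on how arrays were made comparable. With the scale taken without the fragment entries and miR-923, 5 of the 9 were called, and their median moved from -0.65 to -0.51, which leaves open whether entries that rose pull the scale. Without the dim control array all 9 were called, but that fit also redid the scale, and falls numbered 23. The median over tested entries shifted by -0.35 there, which by itself favours calls of falls. Whether the dim array accounts for the falls therefore stays open. Between slides within the UHRF1 siRNA group their median difference was -0.19, with a spread of 0.25, which leaves the slide and scan day open. Within slide 1 their median was -0.43, and with slide as a block 3 of the 9 stayed called. An effect of UHRF1 silencing stays open and untested.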

How the results depend on the processing

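The normexp settings, scaling without fragment entries, slide 1 alone, and median scaling and slide block for lists were chosen after seeing the data. The planned normexp on mean spot signals was not run, since the files hold no such column. The cause was not tested unless stated. Dim signal over background limits these results. Among named entries and lists, 741 comparisons with an alternative kept direction and side of the threshold. Without turning direction, 185 lost a call and 35 gained it. A further 54 turned direction, and some of these also lost or gained a call. miR-1246 and miR-923 stayed called under every alternative run for them (23 and 24), with adjusted p up to 0.0473 and 0.00803.

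Of 32 calls (23 up, 9 down), the total was 16 when scaled over all human entries, 17 without scaling, 14 over entries detected on all arrays (fewer tested), 13 without a filter (more tested), 20 with slide as a block, 7 and 5 with normexp with and without offset, and 12 on slide 1 alone (fewer arrays). Rises numbered 8, 12, 15, 7, 5 and 12 with all-array detection, no filter, no floor, the 2 normexp settings and slide 1. Falls numbered 0, 17, 1, 20 and 18 with scaling over all human entries, quantile normalization, no scaling, median scaling and the deposited table. They numbered 1 without a filter, 3 with the slide block, 17 with array weights, 0 with either normexp, 5 with the scale without fragment entries and 0 on slide 1. Leaving out each array gave 23 to 48 calls, 19 to 25 rises and 3 to 23 falls.

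With the replicate number as a block, 26 were called, 21 up and 5 down, all 26 among the 32. The 6 lost were miR-30d, miR-320a, let-7d, miR-23a, miR-20a and miR-19b. The numbers did not pair the arrays (correlations of deviations -0.41, -0.31 and -0.37).

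The 1 list called became 0 with an estimated correlation, and 2 with quantile normalization, median scaling, total gene signal and the deposited table. With all-array detection the fragment list kept 3 members, all called higher, which were too few to test as a list. Of the 2 lists tested there, 0 were called. The number of lists called was 1 to 2 with each array left out. The difference in detected entries, 24, was 18.5 to 29.5 with each array left out and 9 by positive and significant spots. That in signal, 0.12, was -0.072 with normexp and -0.22 to 0.30 with each array left out.

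Reversals were as follows. Over all human entries, miR-320a, let-7d, miR-23a, let-7a, miR-183, miR-100 and miR-196b were at 0.041, 0.13, 0.13, 0.20, 0.12, 0.18 and 0.20. With normexp and offset, miR-1915, miR-1202, miR-107, miR-31*, miR-29b-1*, miR-125a-5p, miR-15a, miR-638, miR-210 and miR-1280 were at -0.021, -0.025, -0.17, -0.058, -0.17, -0.16, -0.18, -0.13, -0.042 and -0.053. Without offset, miR-107, miR-31*, miR-29b-1*, miR-125a-5p, miR-15a, miR-638 and miR-1280 were at -0.40, -0.034, -0.33, -0.32, -0.36, -0.28 and -0.029. In the deposited table, miR-23b, miR-29a, miR-125a-5p, miR-125b and miR-196b were at 0.85, -0.25, -0.24, -0.045 and 1.06, and with total gene signal miR-23b and miR-196b at 0.049 and 0.26. Median scaling put miR-107, miR-29a and miR-125b at -0.23, -0.025 and -0.043, and quantile normalization miR-107, miR-29a and miR-125a-5p at -0.27, -0.22 and -0.19. With the slide block or slide 1, miR-183 and miR-196b were at 0.022 and 0.10. The miR-17-92 median was -0.22, -0.24, -0.062 and -0.16 with quantile, median scaling, the deposited table and normexp. The let-7 median was 0.023 and 0.042 without scaling and without fragment entries in the scale. The methylation-silenced median was 0.26, 1.06 and 0.10 with total gene signal, the deposited table and slide 1 or slide block. With each array left out, miR-107 ranged from -0.19 to 0.14, miR-15a from -0.059 to 0.68 and the miR-17-92 median from -0.31 to 0.18. Quantile normalization holds the brightest entry, miR-720, at 0 by construction.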

Other observations

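The tests of clusters in this part were chosen after the values were seen, while the count of splits was planned.

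Members of the miR-17-92 cluster, whose 6 genes neighbour each other, also moved apart within arrays. The log2 ratio of miR-20a to miR-17 was 1.59 ± 0.12 in UHRF1 siRNA arrays and 0.57 ± 0.08 in controls (SD, n = 3), a difference of 1.02, and of 1.15 within slide 1. The ratio of miR-19b to miR-92a differed by 1.49, and by 0.88 without control replicate 1. The ratio of miR-20a to miR-92a differed by 0.90, and by 0.56 without that array. Other genes of the same mature miRNAs were not considered. Outside this cluster, the ratio of miR-16 to miR-15b differed by 1.00, and by 0.73 without control replicate 1. That of miR-31* to miR-31, also outside it, differed by 0.36, and the groups overlapped. These ratios show unequal change between entries and do not say which of them changed.

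Of the 10 splits of the 6 arrays into groups of 3, 1 gave as many called entries as the real one, itself included. The real split gave 32 and the highest other gave 0. The splits are too few for a share under 0.05.

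The spike-in entries were listed at 0.1 on all 6 arrays, and the scanner software marked its labelling and hybridization spike-in measures as out of range on all 6 arrays.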
